A study of Homo sapiens with 6 samples.

How the data were processed

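Total RNA of NCI-H1299 cells was sequenced in 6 libraries, 3 with a control hairpin and 3 with a hairpin against ALDH18A1. RNA was extracted with a phenol-based reagent and made into libraries with a TruSeq kit, per the labels' protocols. Their text calls these libraries RIP-seq libraries, although the series is typed as expression profiling and the molecule as total RNA. Reads were trimmed with fastp 0.23.2, aligned with STAR 2.7.10a and counted with featureCounts on the hg38 build, per the submitters' processing notes. Whether counting used strand, and whether ribosomal RNA was removed or poly(A) RNA selected, is not given in the sources used here.

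The file used here is a single comparison table. Its mean normalized count per gene is a signal averaged over libraries and scaled by the authors, per the file headers. Its fold change and SE are on a log2 scale as DESeq2, the tool named by the submitters, reports them, although the authors' header does not state the base. The Wald statistic is a score that the authors deposited, and the p-value and adjusted p-value are the authors' own. The table does not state the numerator of the fold change or the number of libraries behind it. Its up and down calls cover 11914 genes and follow an unadjusted p under 0.05, which lets through adjusted p-values up to 0.106. The deposited adjusted p was used in place of those calls.

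The table has 25289 rows. A pair of symbols stood on 2 rows with equal values, which left 25287 genes, 4937 of them named only by an Ensembl ID. The Wald statistic equals the fold change divided by its SE within 2.24e-13, and the adjusted p equals a Benjamini-Hochberg adjustment over these genes within 1.39e-15. Intervals of 95% were computed as the fold change plus or minus 1.96 SE. Coordinates and gene types come from GENCODE release 29 on GRCh38, which holds 23650 of the genes (93.5%). The precision depends on the count: the median SE was 0.513 for mean counts of 10 to 100, 0.152 for 100 to 1000 and 0.079 for 1000 to 10000. A listed adjusted p of 0 means a value below the smallest number that the file format holds.

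The plan made before the data were examined was an edgeR fit on counts per library, which was not run because no values per library were analysed here. It provided for this case that the deposited comparison be described as the authors' own with no new test per gene, and that was done. The gene list tests depart from the plan. They used cameraPR of limma 3.58.1 in R 4.3.3 on the deposited Wald statistic with a preset correlation of 0.01, two-sided, in place of a test on values per library. Benjamini-Hochberg adjustment ran over the 32 lists, each with at least 5 listed members. The lists hold 1042 genes, of which the table lists 890. Counts "adjusted over the list alone" repeat the adjustment within a list. As a second description, each list median was set among 10000 random lists matched on mean count, drawn within 100 ranks of each member. The same was done among nuclear coding genes with and without a hydrophobic segment apart, chosen after the data were seen. In 50 simulations on shuffled statistics of 25287 genes, 8 lists were shifted by 4 units of the statistic. The list test recovered 59.5% of them, and 3.6% of unshifted lists had an unadjusted p under 0.05. Shuffling removes correlation between genes and any link of the statistic with mean count. These rates therefore do not give the error rate on the unshuffled data.

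Genes were named by a rule fixed before the data were examined. It takes ALDH18A1, then the 10 largest values on each side among genes past the threshold with a mean of at least 5 CPM, a proper symbol and no overlap between the groups' values. It also takes up to 4 members with the smallest adjusted p of each list described, and a set of proline genes that includes PYCR1, PYCR3, PRODH, ALDH4A1 and OAT. Some genes that the rule takes are not reported here. The overlap condition could not be applied, and 5 CPM was taken as a mean normalized count of 215.9. RPLP0 is among the named members of its list. MT-ND1 was named after its value was seen, as were the genes given as context in the closing section.

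Hydrophobic segments were sought in the longest complete coding sequence of each nuclear protein-coding gene, as a window of 19 residues with a mean Kyte-Doolittle hydropathy of at least 1.6. This covered 15203 of 15417 genes (98.6%). A linear model adjusted for GC content, transcript length and mean count with 1000 bootstrap samples. On shuffled values of 15203 genes it returned 0.483 for a difference of 0.5 put in. Shuffling removes any link of the fold change with these 3 properties, so this does not test the adjustment for them. Analyses used Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1. Alternatives were a stricter adjusted p, a minimum fold change, an unadjusted p, a minimum mean count of 10, 2 shifts of the fold changes and other settings of the list tests.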

Results

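RNA sequencing was carried out on total RNA of NCI-H1299 cells, an established human lung cancer line that the labels class as lung adenocarcinoma. The 6 libraries fall into 2 groups of 3, a control short hairpin RNA and a hairpin against ALDH18A1. ALDH18A1 encodes P5CS, the mitochondrial enzyme that turns glutamate into pyrroline-5-carboxylate on the way to proline and ornithine. The series title presents P5CS as an RNA-binding protein that regulates translation, so the comparison asks how the RNA pool differs when its gene is targeted. The values used here are those of the authors' deposited table, which gives 1 mean normalized count, 1 log2 fold change and 1 standard error (SE) per gene. Values and total counts of single libraries were not analysed here, so the depth of each library is unknown. The mean normalized counts of the authors' deposited table add up to 43175646 over 25287 genes, with a median of 63.7 per gene.

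The headers of the authors' deposited table do not name the group in the numerator of the fold change. The targeted gene, which would show the direction, did not pass the threshold. Genes with a log2 fold change above 0 are therefore described as lying on the positive side and those below 0 on the negative side, with no group assigned to either. The labels do not say whether the 3 libraries of a group came from separate cultures, so the p-values may measure technical spread only.

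ALDH18A1 (chromosome 10, 95605929 to 95656706, GRCh38) had a log2 fold change of -0.08 (SE 0.07, DESeq2 adjusted p = 0.471) in the authors' deposited table, at a mean normalized count of 2661. Its 95% interval ran from -0.22 to 0.07, which leaves out a change of a full log2 unit in either direction. With fold changes shifted to equal total counts in the 2 groups, its value was -0.19 and passed the threshold (adjusted p = 0.0227). That shift takes in the difference in mitochondrial RNA described below, so this call depends in part on it. Other genes of proline metabolism did differ. In the authors' deposited table, PYCR1 and PYCR3, which encode enzymes of the last step of proline synthesis, lay on the positive side at 0.61 (SE 0.10, adjusted p = 2.2e-08) and 0.67 (SE 0.18, adjusted p = 0.0007). ALDH4A1, which acts in proline breakdown, lay at 0.96 (SE 0.11, adjusted p = 3.5e-18) in the authors' deposited table. OAT, the ornithine aminotransferase, lay on the negative side of the authors' deposited table at -0.60 (SE 0.07, adjusted p = 1.6e-16). Of the 21 listed genes of proline, ornithine and glutamate metabolism, 9 passed the threshold on the positive side of the authors' deposited table and 7 on the negative side, with the same counts when adjusted over the list alone. The arginase gene ARG2 (3.50, SE 0.19), the collagen prolyl hydroxylase gene P4HA1 (2.01, SE 0.08) and P4HA2 (0.80, SE 0.07) were on the positive side of the authors' deposited table, and the glutamate dehydrogenase gene GLUD1 (-0.62, SE 0.06) on the negative side. The list as a whole did not stand apart from other genes (adjusted p = 0.281, cameraPR). PRODH was not analysed here.

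A large part of the measured RNA pool differed in the comparison that the authors' deposited table holds. That it sets knockdown against control is taken from the labels, since its headers do not name the groups. In the authors' deposited table, 10718 of 25287 genes (42.4%) had an adjusted p under 0.05, 5283 on the positive side and 5435 on the negative side. An absolute log2 fold change of at least 1 was reached by 4550 of them, 2765 positive and 1785 negative. Among genes with a mean of at least 5 CPM (counts scaled to the table's total), the positive side of the authors' deposited table was led by DHRS3, a retinal reductase gene (5.46, SE 0.23), the peptide receptor gene VIPR1 (4.99, SE 0.29) and the sialyltransferase gene ST8SIA4 (4.81, SE 0.25). TMEM158 (4.50, SE 0.09), SLITRK5 (4.49, SE 0.22), the growth factor midkine, MDK (4.25, SE 0.09), SEMA6B (4.24, SE 0.13), B4GALNT4 (4.20, SE 0.16), CYBRD1 (4.19, SE 0.10) and the matrix glycoprotein gene THBS1 (4.17, SE 0.14) completed the 10 largest positive values under the naming rule in the authors' deposited table. On the negative side of the authors' deposited table, the protein-coding genes were AMHR2 (-7.16, SE 0.80), the kinesin gene KIF1A (-5.23, SE 0.17), the potassium channel subunit gene ABCC9 (-5.13, SE 0.34), the TNF receptor family gene TNFRSF9 (-5.00, SE 0.08), the calponin gene CNN1 (-4.98, SE 0.29), the integrin gene ITGAM (-4.00, SE 0.18) and SOCS2 (-3.89, SE 0.16). Adjusted p-values of these 17 protein-coding genes were 4.3e-18 or lower in the authors' deposited table. The processed pseudogenes HSPE1P10 (-8.50, SE 0.47) and RPLP0P2 (-4.17, SE 0.18) and the noncoding RNA gene LINC02154 (-4.10, SE 0.31) made up the rest of the 10 largest negative values under the naming rule in the authors' deposited table. Reads of processed pseudogenes can come from their parent genes. RPLP0, the parent of RPLP0P2, lay at -0.61 (SE 0.07) in the authors' deposited table, and HSPE1 was not analysed here.

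**Figure D1:**
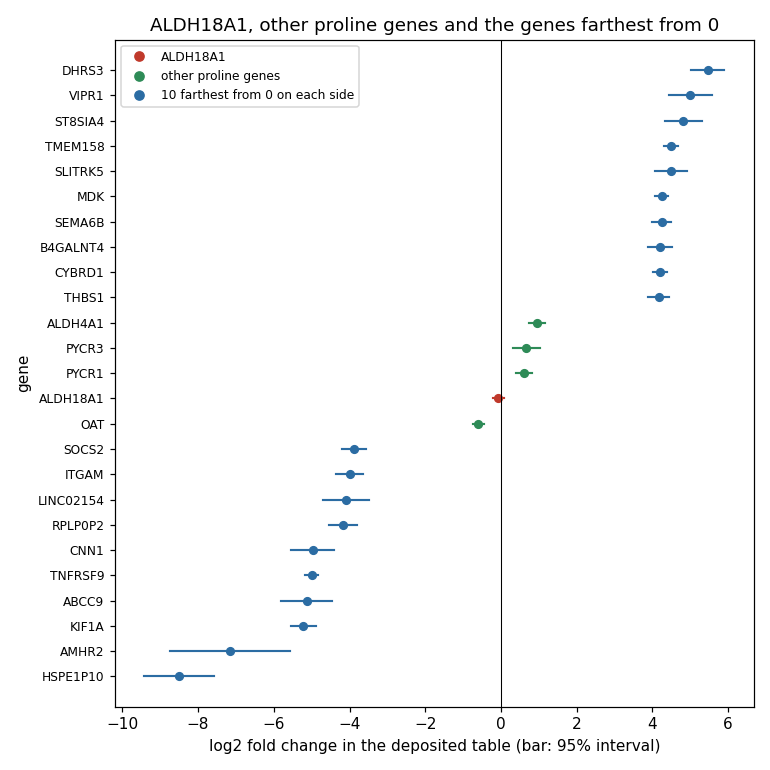
The horizontal axis is the log2 fold change of the authors' deposited table, with a point per gene and a bar for its 95% interval. ALDH18A1 sits at -0.08 with a bar that crosses 0, and the 4 other proline genes lie between -0.60 and 0.96. The 10 genes farthest from 0 on each side start at 4.17 and -3.89. They were taken among genes past the threshold with a mean of at least 5 CPM and a proper symbol. Genes outside these limits can lie farther out.

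All 13 mRNAs of the mitochondrial genome lay on the positive side of the authors' deposited table and passed the threshold, with a median log2 fold change of 1.59. MT-ATP6, a subunit of the ATP synthase, was highest at 2.25 (SE 0.07), or 4.77-fold, followed in adjusted p by MT-ATP8 (1.96, SE 0.08), MT-ND3 (1.70, SE 0.08) and MT-CYB (1.67, SE 0.08) in the authors' deposited table. The lowest of the 13 was MT-ND1 at 0.24 (SE 0.07) in the authors' deposited table, which did not pass with equal total counts (adjusted p = 0.155). By the fold changes and mean counts of the authors' deposited table, and with equal group sizes assumed, these 13 mRNAs made up 15.91% of the counts on the positive side of the comparison and 6.24% on the other. The list stood apart from other genes (adjusted p = 5.79e-20, cameraPR, and 3.51e-10 with a preset correlation of 0.1). Random lists matched on mean count cannot place it. Draws that ran past the most abundant gene returned that gene, so these lists largely repeated it. Their usual median was -0.311, the value of that gene, ENSG00000280441. That the list median lay above all 10000 of them therefore decides nothing. Several nuclear-retained RNAs lay on the same side of the authors' deposited table, among them NEAT1 (2.58, SE 0.09) and MALAT1 (1.95, SE 0.24). Nuclear genes of oxidative phosphorylation did not move with them. Of 59 in the authors' deposited table, 15 were positive, 18 were negative and 26 did not pass, with a median of 0.01 that turns to -0.11 with equal total counts (adjusted p = 0.757). UQCRC1 (1.15, SE 0.07) and NDUFB11 (1.15, SE 0.11) lay on the positive side of the authors' deposited table, and NDUFV1 (-0.70, SE 0.07) and NDUFA8 (-0.80, SE 0.09) on the negative side. Mitochondrial ribosomal protein genes were divided as well, with 10 positive and 27 negative of 59 in the authors' deposited table and a median of -0.17. Their test did not pass (adjusted p = 0.113, cameraPR) but passed with equal total counts (adjusted p = 0.0338) and with ranks (adjusted p = 0.038). The median lay at percentile 41.77 of random lists matched on mean count, and at 84.16 when matched on a hydrophobic segment as well. MRPL36 (2.23, SE 0.14) and MRPL32 (1.53, SE 0.09) stood against MRPL15 (-1.25, SE 0.07) and MRPL37 (-1.30, SE 0.07) in the authors' deposited table.

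Genes of the unfolded protein response, which serve folding and quality control in the endoplasmic reticulum, were mostly positive. Of 27 in the authors' deposited table, 23 passed on the positive side and 2 on the negative side, with a median of 0.72. HERPUD1 (1.32, SE 0.08), DNAJB11 (1.18, SE 0.07), PDIA6 (1.14, SE 0.05) and the transcription factor gene XBP1 (1.05, SE 0.06) had the smallest adjusted p-values of this list in the authors' deposited table. The list stood apart from other genes (adjusted p = 2.88e-09, cameraPR; 0.00256 with a correlation of 0.1), and its median lay at the 99.98th percentile of random lists matched on mean count. However, 21 of its 27 members encode a hydrophobic segment, and the 5720 nuclear genes that do had a median of 0.294 in the authors' deposited table, against -0.174 for 9483 others. Among random lists matched on this segment as well, its median lay at percentile 96.06, inside the central 95%. Collagen and matrix genes had 20 of 41 on the positive side of the authors' deposited table and 11 on the negative side, with a median of 0.28 (adjusted p = 0.00349; 0.223 with a correlation of 0.1), at percentile 88.15 of lists matched on count and segment. The lysyl oxidase gene LOXL2 (3.48, SE 0.06) and COL13A1 (3.88, SE 0.17) lay with THBS1 on the positive side of the authors' deposited table, and TGFBI (-2.07, SE 0.08) on the negative side. Mesenchymal genes had 11 of 20 positive and 6 negative in the authors' deposited table, with a median of 0.56 (adjusted p = 0.00503; 0.153 with a correlation of 0.1), at percentile 80.54 of lists matched on count and segment. Their abundant members NT5E (1.81, SE 0.05), the receptor kinase gene AXL (1.43, SE 0.06) and CCN1 (1.57, SE 0.06) were positive in the authors' deposited table, while CNN1 was among the largest negative values. Epithelial junction genes did not stand apart, with 5 of 23 positive and 4 negative in the authors' deposited table (adjusted p = 0.547). CLDN1 (1.44, SE 0.06) and OCLN (1.49, SE 0.07) lay opposite TJP1 (-1.48, SE 0.06) and DSP (-1.15, SE 0.08) in the authors' deposited table.

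Genes of the cytosolic translation machinery passed more often on the negative than on the positive side. Of 44 translation initiation, elongation and termination factors, 30 were negative and 6 positive in the authors' deposited table, with a median of -0.40 (adjusted p = 4.43e-06, cameraPR; 0.0454 with a correlation of 0.1). EIF4EBP2, which encodes a repressor of cap-dependent initiation, lay at -1.46 (SE 0.06) in the authors' deposited table. The termination factor gene ETF1 (-1.32, SE 0.06), EIF6 (-1.26, SE 0.07) and EIF3B (-1.18, SE 0.06) were also negative in the authors' deposited table. Cytosolic aminoacyl-tRNA synthetases had 17 of 23 negative and 3 positive in the authors' deposited table, with a median of -0.44 (adjusted p = 8.3e-05; 0.0454 with a correlation of 0.1). HARS1 (-0.83, SE 0.06), GARS1 (-0.82, SE 0.06) and NARS1 (-0.70, SE 0.06) were among its negative members in the authors' deposited table. Ribosome biogenesis genes had 22 of 35 negative and 4 positive in the authors' deposited table, with a median of -0.39 (adjusted p = 0.00136; 0.153 with a correlation of 0.1). BOP1 (-1.14, SE 0.08), the helicase gene DDX21 (-0.99, SE 0.05) and TCOF1 (-0.73, SE 0.06) were negative, and NOP58 (1.71, SE 0.08) was positive, in the authors' deposited table. Among ribosomal protein genes, 20 of 41 of the large subunit and 13 of 30 of the small subunit were negative in the authors' deposited table, and 3 and 1 were positive. Their medians were -0.20 and -0.18 in the authors' deposited table, and neither list passed (adjusted p = 0.0851 and 0.173). Both passed with ranks of the statistic (adjusted p = 0.00857 and 0.0298), and the large subunit also with equal total counts (adjusted p = 0.0186). RPL11 (-0.79, SE 0.07), RPL4 (-0.68, SE 0.06), RPSA (-0.62, SE 0.07) and RPS3A (-0.70, SE 0.09) were among the named members of the authors' deposited table. These genes have many pseudogenes that can share their reads. Random lists matched on mean count put the median of the initiation and elongation factors at percentile 1.73, that of the synthetases at 7.41 and that of ribosome biogenesis at 6.63. Matched on segment as well, these became 33.34, 10.93 and 15.72. The 5706 genes with a mean count of at least 1000 had a median of -0.19 in the authors' deposited table.

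NRF2 and NF-kappaB targets passed more often on the negative than on the positive side. NRF2 targets, which defend against oxidants, had 17 of 26 negative and 6 positive in the authors' deposited table, with a median of -0.66 (adjusted p = 1.28e-05, cameraPR; 0.0439 with a correlation of 0.1). TXNRD1 (-2.26, SE 0.06), the heme oxygenase gene HMOX1 (-2.07, SE 0.08), GCLM (-1.80, SE 0.09) and OSGIN1 (-1.65, SE 0.09) had the smallest adjusted p-values of the list in the authors' deposited table. NF-kappaB targets and cytokines had 10 of 21 negative and 5 positive in the authors' deposited table, with a median of -1.01 (adjusted p = 8.3e-05; 0.0454 with a correlation of 0.1 and 0.0548 with ranks). TRAF1 (-2.57, SE 0.09), the inhibitor gene NFKBIA (-2.53, SE 0.11), RELB (-1.59, SE 0.07) and NFKB2 (-1.44, SE 0.06) were negative in the authors' deposited table. The medians of the 2 lists lay at percentiles 0.06 and 0.0 of random lists matched on mean count, and at 0.03 and 0.0 when matched on segment as well. Lysosome and autophagy genes split, 17 negative and 13 positive of 34 in the authors' deposited table, with a median of -0.26. Their test passed (adjusted p = 0.000893, cameraPR) but not with a correlation of 0.1 (adjusted p = 0.153) or with ranks (adjusted p = 0.396). The median lay at percentile 21.02 of random lists matched on mean count, and at 13.94 when matched on segment as well. The negative members included the autophagy receptor genes SQSTM1 (-2.24, SE 0.06) and OPTN (-2.18, SE 0.07), with ATP6V1B2 (-1.67, SE 0.07) and ATG13 (-1.25, SE 0.06), in the authors' deposited table. Polyamine genes had 8 of 13 negative and 3 positive in the authors' deposited table, with a median of -0.52 (adjusted p = 0.00253; 0.0717 with a correlation of 0.1). Both the ornithine decarboxylase gene ODC1 (-1.34, SE 0.06) and the catabolic gene SAT1 (-1.71, SE 0.09) were negative in the authors' deposited table. p53 target genes had 10 negative and 7 positive of 21 in the authors' deposited table, with a median of -0.08 at percentile 50.15 of matched random lists. Their test passed (adjusted p = 0.0123, cameraPR) but not with a correlation of 0.1 (adjusted p = 0.212) or with ranks (adjusted p = 0.408). Members with large values were PLK2 (-2.71, SE 0.08), GADD45A (-2.26, SE 0.07) and CDKN1A (-1.90, SE 0.08), with FAS (2.27, SE 0.10) opposite, in the authors' deposited table. Which members the call depends on was not tested. Apoptosis regulators had 15 negative and 8 positive of 27 (adjusted p = 0.0851) and immediate early genes 10 negative and 7 positive of 22 (adjusted p = 0.0841) in the authors' deposited table. Both passed with equal total counts (adjusted p = 0.0338 and 0.0301). XIAP (-1.46, SE 0.07), JUN (-1.22, SE 0.06) and KLF2 (2.32, SE 0.11) were members named from these lists in the authors' deposited table.

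The ATF4 amino acid response did not move as a block, with 16 positive and 8 negative of 31 in the authors' deposited table and a median of 0.28 (adjusted p = 0.107). The glutamine transporter gene SLC1A5 was positive (2.20, SE 0.07), whereas ATF3 (-2.29, SE 0.08), SESN2 (-1.64, SE 0.07) and PPP1R15A (-1.33, SE 0.06) were negative in the authors' deposited table. Glycolysis and hypoxia genes had 9 positive and 13 negative of 27 in the authors' deposited table, and their median of -0.22 and mean of 0.04 differ in sign (adjusted p = 0.601). The glucose transporter gene SLC2A1 (3.42, SE 0.07) and the lactate exporter gene SLC16A3 (1.43, SE 0.07) lay opposite HK1 (-0.92, SE 0.07) in the authors' deposited table. Cholesterol synthesis genes had 12 positive and 4 negative of 24 in the authors' deposited table (median 0.16, adjusted p = 0.173), with TM7SF2 (2.14, SE 0.11) on the positive side and HMGCS1 (-1.23, SE 0.06) and MVD (-1.27, SE 0.07) on the negative side. S phase genes had 8 positive and 19 negative of 42 (adjusted p = 0.173; 0.0481 with equal total counts) and G2/M genes 16 positive and 24 negative of 52 (adjusted p = 0.577) in the authors' deposited table. TYMS (1.605, SE 0.11) and UNG (-1.33, SE 0.07) of the first list, and CDCA3 (1.14, SE 0.08) and RANGAP1 (-1.19, SE 0.06) of the second, passed in opposite directions in the authors' deposited table. Interferon response genes had 9 positive and 5 negative of 30 (adjusted p = 0.505) in the authors' deposited table, with IFI6 at 2.49 (SE 0.13) and ISG20 at -1.88 (SE 0.21). Hosts of small nucleolar RNAs and targets of nonsense-mediated decay had 11 positive and 6 negative of 24 in the authors' deposited table, with a median of 0.45 at percentile 99.45 of matched random lists (adjusted p = 0.408). SNHG12 (1.36, SE 0.13) and TBL2 (1.73, SE 0.06) were positive and UPP1 (-1.98, SE 0.06) negative in the authors' deposited table. Replication-dependent histones, most of which lack poly(A) tails, had 3 positive and 6 negative of 23 in the authors' deposited table (median -0.19, adjusted p = 0.522).

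Markers of other cell types did not stand apart as lists. Immune cell markers had 2 positive and 3 negative of 11 in the authors' deposited table (adjusted p = 0.475), at a median mean count of 9.8. ITGAM, among the largest negative values above, and CSF1R (-1.29, SE 0.44) were negative and CD14 (2.33, SE 0.58) and CD79A (2.40, SE 0.59) positive in the authors' deposited table. Fibroblast and endothelial markers had 3 positive and 1 negative of 16 (adjusted p = 0.757) and lung epithelial markers 1 positive of 10 (adjusted p = 0.757) in the authors' deposited table. The endothelial gene PECAM1 (2.53, SE 0.28) and the fibroblast gene DCN (2.54, SE 0.55) were positive and the endothelial gene KDR (-1.67, SE 0.38) negative in the authors' deposited table, at mean counts of 116.1, 24.0 and 49.8. Markers of neurons and of a kidney packaging line had 1 positive and 5 negative of 13 in the authors' deposited table (adjusted p = 0.294). The neuronal genes INA (-1.11, SE 0.06) and STMN2 (-2.33, SE 0.58) and the kidney gene LHX1 (-1.31, SE 0.30) were negative in the authors' deposited table. UCHL1, abundant at a mean count of 10897, was the positive one at 0.19 (SE 0.07) in the authors' deposited table, and it no longer passed with equal total counts.

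When adjusted over the list alone, the counts above changed by at most 2 genes per side in any list. Median and mean differ in sign for 6 lists, none of which passed: nuclear oxidative phosphorylation, glycolysis and hypoxia, epithelial junctions, histones, fibroblast and endothelial markers, and lung epithelial markers. The test took the sign of the mean statistic, opposite to the median, for nuclear oxidative phosphorylation, glycolysis and hypoxia, and fibroblast and endothelial markers. Of 32 lists, 12 passed an adjusted p of 0.05 over the lists. The 6 that also passed with a correlation of 0.1 were mitochondrial mRNAs, unfolded protein response, translation factors, aminoacyl-tRNA synthetases, NRF2 targets and NF-kappaB targets. With the log2 fold change as the statistic, 2 lists passed, mitochondrial mRNAs (adjusted p = 0.00353) and NF-kappaB targets (adjusted p = 0.0428). Of 31 lists with nuclear coding members, 6 lay outside the central 95% of random lists matched on count and segment. These were NRF2 and NF-kappaB targets and apoptosis regulators (percentile 2.28) on the low side, and ATF4 (98.07), interferon response (97.69) and G2/M genes (99.12) on the high side. A correlation between genes could not be estimated without values per library. Equal total counts in the 2 groups would shift every log2 fold change by 0.12 toward the negative side, and only the medians of epithelial junction genes and nuclear oxidative phosphorylation genes change sign with it.

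**Figure D2:**
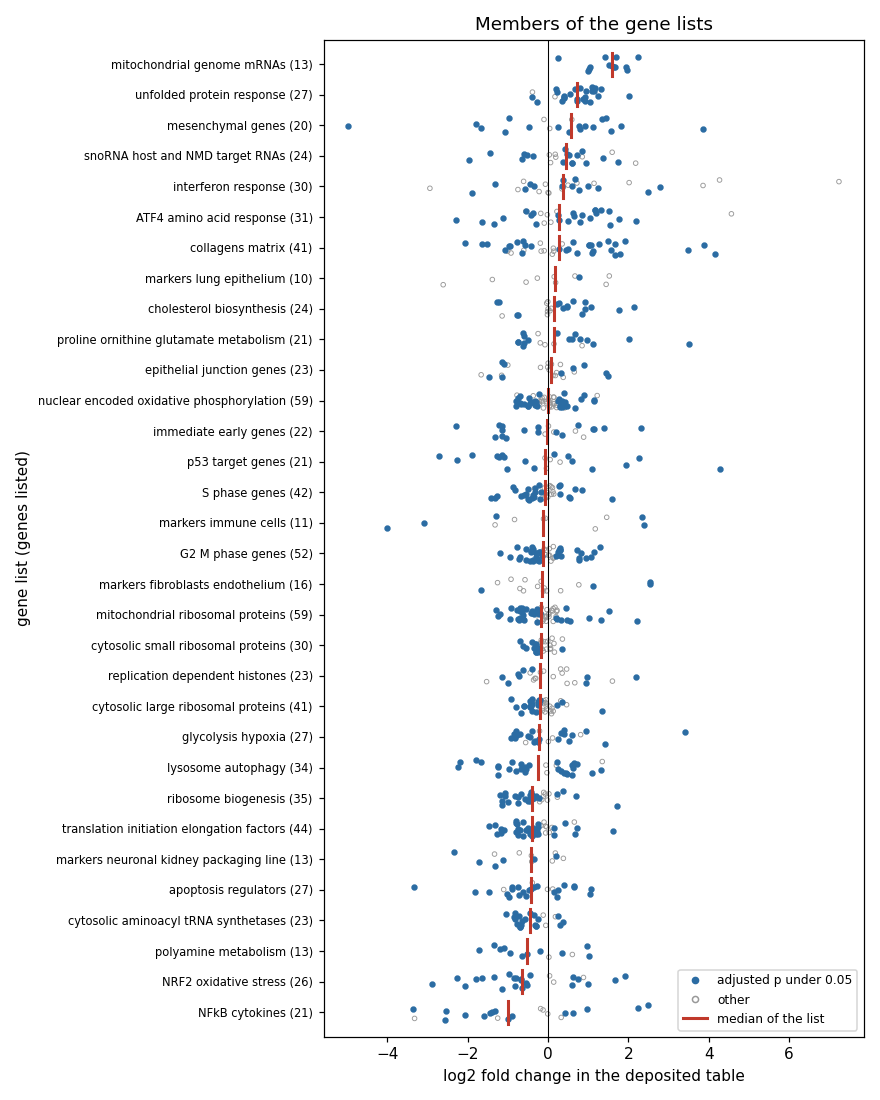
Each row is a gene list and each point a member, at its log2 fold change in the authors' deposited table; filled points have an adjusted p under 0.05 and red lines mark list medians. Medians run from 1.59 for mitochondrial mRNAs to -1.01 for NF-kappaB targets and cytokines.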

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

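The stricter adjusted p and the minimum fold change were planned; all other alternatives were chosen after seeing the data. With an absolute log2 fold change of at least 1, the count of genes past the threshold was 4550, with 2765 on the positive side and 1785 on the negative side, because the alternative adds a condition. Under the other 5 settings the count stayed within 1.5 times the main one, from 9139 at an adjusted p under 0.01 to 11914 at an unadjusted p under 0.05. Equal total counts moved the split to 4580 positive and 6313 negative (42.0% positive against 49.3%). ALDH18A1 lay at -0.19 with equal total counts and passed there (adjusted p = 0.0227). The cause was not tested beyond the shift itself. The totals were derived from fold changes and mean counts, with equal group sizes assumed, and they include the mitochondrial genome. It held 18.05% of the total on the positive side and 8.14% on the negative side. Calls gained or lost with equal total counts therefore depend in part on that difference. The 12 lists past the threshold became 6 with a correlation of 0.1, which widens the null by construction, and 2 with the log2 fold change as the statistic, where the cause was not tested. Matched random lists set 6 lists apart, 5 of these 12 and the hosts of small nucleolar RNAs. The cause was not tested. Mitochondrial mRNAs are among the 5, and their place decides nothing because their matched lists largely repeat the most abundant gene. Matching on a hydrophobic segment as well also set 6 of 31 apart but only 2 of these 12. Genes with such a segment lie higher as a class, but this setting also kept only nuclear coding genes. It thereby left out the mitochondrial mRNAs and some members of other lists, so the cause of the change was not isolated. Equal total counts gave 17 lists, with 5 calls gained and none lost. Ranks gave 9, with 3 calls gained and 6 lost, and a correlation of 0.05 gave 10. No list call reversed under the 6 settings of the list test. Of 167 named genes besides ALDH18A1, 2 Ensembl IDs of chromosome 21 gained a call with either shift, UCHL1 and MT-ND1 lost it with equal total counts, and the others kept theirs under the shifts and at an adjusted p under 0.01; 46 lost their call with the minimum fold change. No paired analysis was possible because no values per library were analysed here. For the same reason leaving out each library, other normalizations, other count models, filters per library, other splits of the samples, fry and an estimated correlation were not run. Precision limits low genes: at mean counts of 10 to 100 the median SE of 0.513 hides differences that pass easily at 1000 to 10000, where it was 0.079.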

Other observations

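Of the tests reported here, those of exchanged libraries, of another contrast, of hydrophobic segments (the comparison, its adjusted model, its second cut and the lists matched on it), of organelle-bound and nuclear RNA and of overlapping genes were chosen after the result was seen, as were the genes and RNA classes of the next 2 paragraphs.

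Of 12 RNAs listed as retained in the nucleus, 9 passed on the positive side and none on the negative side of the authors' deposited table, with a median of 0.67 and no test of the list. Of the 9, 4 are copies of the gene of U3 small nucleolar RNA: SNORD3A (1.46, SE 0.11), SNORD3B-1 (1.499, SE 0.15), SNORD3B-2 (0.48, SE 0.09) and SNORD3C (1.54, SE 0.13) in the authors' deposited table. LINC-PINT (0.17, SE 0.11), PVT1 (0.04, SE 0.09) and MEG3 (-0.39, SE 1.39) did not pass in the authors' deposited table. The paraspeckle RNA NEAT1 lay at 2.58 (SE 0.09), MALAT1 at 1.95 (SE 0.24), TUG1 at 0.72 (SE 0.07), the RNA of RNase MRP, RMRP, at 0.63 (SE 0.12) and FTX at 0.58 (SE 0.15) in the authors' deposited table. The mitochondrial rRNAs MT-RNR1 (0.36, SE 0.06) and MT-RNR2 (0.26, SE 0.06) were also positive in the authors' deposited table, but by less than most mitochondrial mRNAs. Processed pseudogenes had 80 positive and 225 negative of 1914, and antisense genes 284 positive and 134 negative of 1559, in the authors' deposited table. Whether counting used strand is not known, so reads of antisense genes and their partners cannot be separated.

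Genes often used as references did not behave alike. ACTB lay at -0.61 (SE 0.06, adjusted p = 4.7e-22), GAPDH at 0.41 (SE 0.06, adjusted p = 8.6e-11) and ENO1 at 0.01 (SE 0.06, adjusted p = 0.926) in the authors' deposited table. The chaperonin gene HSPD1 lay at -0.33 (SE 0.06), far from the -8.50 of the HSPE1 pseudogene HSPE1P10, in the authors' deposited table. A gene of chromosome 21 (ENSG00000280441, 8380665 to 8410645), typed as lincRNA by the annotation used here, had a mean normalized count of 4834458. It thus holds a large part of all counts in the authors' deposited table. Which RNA its reads come from was not tested, and whether ribosomal RNA was removed is not known. The gene did not pass, at a log2 fold change of -0.31 (SE 0.14, adjusted p = 0.062) in the authors' deposited table. It passed with equal total counts (adjusted p = 0.00634) and with the median of all genes at 0 (adjusted p = 0.0342). ENSG00000278996 (-0.32, SE 0.14, adjusted p = 0.0634) likewise passed only with either shift, and ENSG00000281383 passed at -0.50 (SE 0.06, adjusted p = 5.4e-14) in the authors' deposited table.

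ALDH18A1 did not pass the threshold although 10718 other genes did. A partial exchange of libraries between 2 groups of 3 would make each group a mixture and keep ratios of group means between 0.5 and 2, but 9.26% of genes have a 95% interval wholly beyond 1 on the log2 scale, and a full exchange would only turn the sign. Reads shared with a near-identical copy are argued against, since 0.0% of the 50-base words of its longest transcript occur in transcripts of other genes, against 22.78% for RPLP0. That the table may hold another contrast than knockdown against control stays open, because the value of -0.0754 is what such a contrast would give and no value here decides it. The same value would arise if the hairpin had not lowered ALDH18A1 RNA, and that stays open as well. The differences of other genes therefore cannot be credited here to a loss of ALDH18A1. A knockdown that acts on the protein rather than the RNA was not tested.

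Genes that encode a hydrophobic segment, as most membrane and many secreted proteins have, passed more often on the positive side. Of 5720 such nuclear genes 37.1% passed on the positive side and 16.7% on the negative side, against 19.8% and 38.8% of the 9483 others, and the difference of medians was 0.468 (permutation p = 0.0001, the smallest that 10000 permutations can give, over genes that are not independent). GC content, transcript length and mean count do not account for it, since the adjusted difference was 0.434 (95% interval 0.398 to 0.469; 0.525 with a hydropathy of 2). An equal gain of all organelle-bound and nuclear RNA would not alone place MT-ND1 at 0.24 and MT-ATP6 at 2.25 in the authors' deposited table. The mitochondrial rRNAs, only 2 genes, had the lowest median of the 3 classes, 0.31, but cannot decide it. Whether ribosomal RNA was removed is not known, so their counts may be what removal left. An unequal gain by RNA quality or lysis, which could also lie behind the mitochondrial mRNAs and nuclear-retained RNAs, stays open, and so does the hypothesis that RNA translated at the endoplasmic reticulum may differ as a class from cytosolic RNA in the cells, which only values per library or per fraction would test.

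Some housekeeping genes were not analysed here because the table as used here does not list them. They are 52 (15.2%) of 343 genes in 7 lists of translation and respiration. Low expression of these genes stays open: 0.69% of the listed members had a mean count under 20, which says nothing of the unlisted ones. A symbol shared by more than 1 gene is argued against, at 0.0% of the unlisted genes. Overlap with another annotated gene may contribute, since 51 of the 52 overlap one, against 194 of 291 listed genes, a difference of 31.4 percentage points (Fisher's exact p = 1.8e-07, two-sided). Overlap alone does not say why a gene is unlisted, and no biological explanation was tested.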
